A study of Rattus norvegicus with 3 samples.

How the data were processed

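Gene expression was measured in the medullary thick ascending limb (mTAL), the segment of the kidney tubule in the outer medulla that reabsorbs sodium chloride without water. The tissue came from male Sprague-Dawley rats 7 to 8 weeks of age. Per the labels' protocols, each rat was given heparin (250 u) and the loop diuretic furosemide (1 mg) into the peritoneum 30 min before it was killed. The kidneys were perfused with 10 ml of cold buffered saline and then with 10 ml of warm solution holding 1 mg/ml collagenase and 0.5 mg/ml hyaluronidase. The outer medulla was cut out, digested for 60 min under 95% oxygen and 5% carbon dioxide, and the mTAL was taken from a gradient of 33.3% Percoll. Total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised to Affymetrix arrays, per the labels' protocols. The 3 samples form 1 group, and their replicate numbers were taken from the sample titles. No label says whether the 3 samples came from separate rats or from pools, so p-values measure only the spread between these samples, which may be technical.

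The authors deposited 1 intensity value per probe set and array on a linear scale, and the summary method, its software and any normalization between arrays were not given in the sources used here. The values ran from 0.217 to 94710. After the lowest and highest 2% of values were left out, the mean signal of the 3 arrays was 1000.4, 1000.3 and 1000.3, so that all arrays had one overall scale. The median signal was 256, 287 and 267 for replicates 1, 2 and 3. No value was 0 or negative, so log2 was taken without a pseudocount and with no further scaling.

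The table held 31099 probe sets, of which 57 were controls. The platform annotation gave 1 gene to 20826 probe sets, several to 436 and none to 9780, and only those with 1 gene were used. The identifiers of 20758 of these probe sets were found in the RefSeq gene table of the rat assembly GRCr8, which changed none of their symbols. The probe sets covered 14217 genes. For the 4525 genes with more than 1 probe set, the probe set with the highest mean log2 signal stood for the gene. Because probe sets differ in how strongly they hybridise, orders of genes and of gene lists describe signals, not the relative abundance of transcripts. No genome coordinates are given.

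A gene was called detected when its signal lay above a cutoff that was set on each array by itself. The cutoff was the 95th percentile of 70 measured genes known from tissues such as brain, pituitary, pancreas, muscle, retina, gonads and skin. The log2 signal minus the array's cutoff was tested with limma (lmFit and eBayes, one-sided, above 0), and p-values were adjusted by the method of Benjamini and Hochberg over all 14217 genes at a threshold of 0.05. On simulated data with the measured levels and spreads, this test called 70, 96, 98 and 100 of 100 genes placed 0.5, 1, 2 and 4 log2 units above the cutoff. Of 7162 simulated calls among 14217 genes, 6 were of genes at or below the cutoff. For genes not placed, the simulation took the measured mean as the true level, and it took the cutoff as known. It therefore covers only the spread between arrays. The share of detected genes that are not expressed, and the error of the cutoff itself, cannot be read from it. The number of arrays limits the precision of every value.

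The 27 gene lists, the tests, the rule for naming genes and all alternatives except those said to be added later were fixed before the data were examined. Of the 473 list entries, 412 matched a measured gene. List entries without a match are not analysed here. Counts of detected genes per list were adjusted over all genes and also over the list alone. The level of a list was the median over its genes of log2 signal minus the array's median gene, with its percentile among 10000 random lists of the same size. The level of the thick ascending limb (TAL) list was compared with that of 10 lists of other cell types by an exact sign-flip permutation test, two-sided, for which 3 arrays allow no p below 0.25. The deviation of an array was the median over a list of its log2 value minus the mean of the other arrays, each array centred on its median gene. It was set beside 10000 random lists matched on mean level and has no p-value, since 1 array cannot be tested against the others. Lists shared genes: 9 of the 14 TAL markers, 2 of the 23 proximal tubule markers and 4 of the 12 principal cell markers also stood in another list.

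The text names all measured TAL markers and, of every other list, the 3 detected genes with the highest signal. Of the sodium pump, tight junction, receptor, adenylyl cyclase, potassium channel and acid-base lists it also names the 2 genes with the lowest signal. It further names the 20 genes with the highest signal and the 10 detected genes with the largest SD. A gene named outside this rule is said to have been chosen after its values were seen. The alternatives were quantile normalization, a common 75th percentile, a pseudocount of 16, the median over a gene's probe sets, leaving out probe sets that can match several transcripts, leaving out each array in turn, other cutoffs and another detection rule. The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.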

Results

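The transcripts of the rat mTAL were profiled on 3 Affymetrix arrays, all of 1 group, and no other tissue or treatment was included. The purpose, per the series description, was to obtain the transcriptome of this segment. The questions that such a design allows are which genes were seen above background, how closely the 3 preparations agreed, and how far markers of the segment stood above markers of other kidney cells. The values are probe set signals on a linear scale with a trimmed mean of about 1000 per array, given as mean ± SD over the 3 arrays (n = 3 throughout).

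Transcripts of 6862 of the 14217 measured genes, or 48.3%, were detected above the background of genes from other tissues. The cutoff lay at a signal of 562 on replicate 1, 501 on replicate 2 and 503 on replicate 3. The 20 genes with the highest signal included the mitochondrially encoded cytochrome oxidase subunits COX1 (68882 ± 11722) and COX2 (67173 ± 9937), Umod (57036 ± 8031), the mitochondrial isocitrate dehydrogenase Idh2 (53334 ± 651) and the sodium pump subunit Atp1b1 (53319 ± 7183). The others were Rps29, Itm2b, Atp5f1b, Aldoa, Ppp1r1a, Ldhb, Cox8a, Actg1, Cox7b, Rpl7a, Egf, Atp5f1c, Cox4i1, Atp5mc3 and Ndufb9, with mean signals from 52119 for Rps29 to 44645 for Ndufb9. The SD over the arrays had a median of 0.25 log2 units over all genes. It was 0.15 for the 7710 genes with a mean log2 signal above the mean cutoff, of which 95.3% had an SD under 0.5, and 0.58 for the others; detected genes were not used for this, since detection itself depends on the SD. Pearson's r across probe sets, which are not independent replicates, was 0.925 between replicates 1 and 2, 0.923 between replicates 1 and 3, and 0.927 between replicates 2 and 3. The number of detected genes depended on the cutoff, with 723 genes at the 99th percentile of the other-tissue genes and 11138 at the highest signal of TrpnX, a control transcript that is not added to samples. The 99th percentile lies between Cela1 (1800 ± 324) and Myh1 (42933 ± 2949), the highest of the other-tissue genes. Counts at that cutoff therefore depend on Myh1, whose annotation is in question. The main cutoff also rests on few genes. It lay between the signals of Lhb (444, 302 and 361 on replicates 1, 2 and 3) and Mbp (682, 756 and 659). Both genes were named after their values were seen. Myh1 ranked above both, so its place in the list also affects the main cutoff and every count that uses it. Counts without Myh1 in the list were not computed.

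All 14 measured TAL markers were detected, also when adjusted over the list alone. Umod, the gene of the urinary protein uromodulin, had a signal of 57036 ± 8031, 6.76 log2 units above the cutoff. Egf (45192 ± 905) and Slc12a1 (39427 ± 2562), the furosemide-sensitive sodium, potassium and chloride cotransporter, stood 6.44 and 6.24 above it. The apical potassium channel Kcnj1 had a signal of 16469 ± 5733 and the chloride channel subunit Bsnd one of 6480 ± 107. The claudins of the segment, which form its paracellular path for cations, had signals of 36920 ± 1939 (Cldn10), 9940 ± 777 (Cldn19) and 6437 ± 1102 (Cldn16). The receptors Ptger3, for prostaglandin E2, and Casr, for extracellular calcium, had signals of 13250 ± 1258 and 9308 ± 3004. The transcription factors Pou3f3 (9615 ± 1527), Irx1 (7298 ± 649) and Irx2 (2031 ± 428) and the membrane protein gene Tmem72 (2136 ± 326) made up the rest. The limma adjusted p of the 14 genes ran from 0.000138 for Umod to 0.000923 for Irx2. The list as a whole lay 3.88 ± 0.21 log2 units above the median gene, higher than all 10000 random lists. With the cutoff at the 99th percentile, 7 of the 14 were detected.

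**Figure D1:**
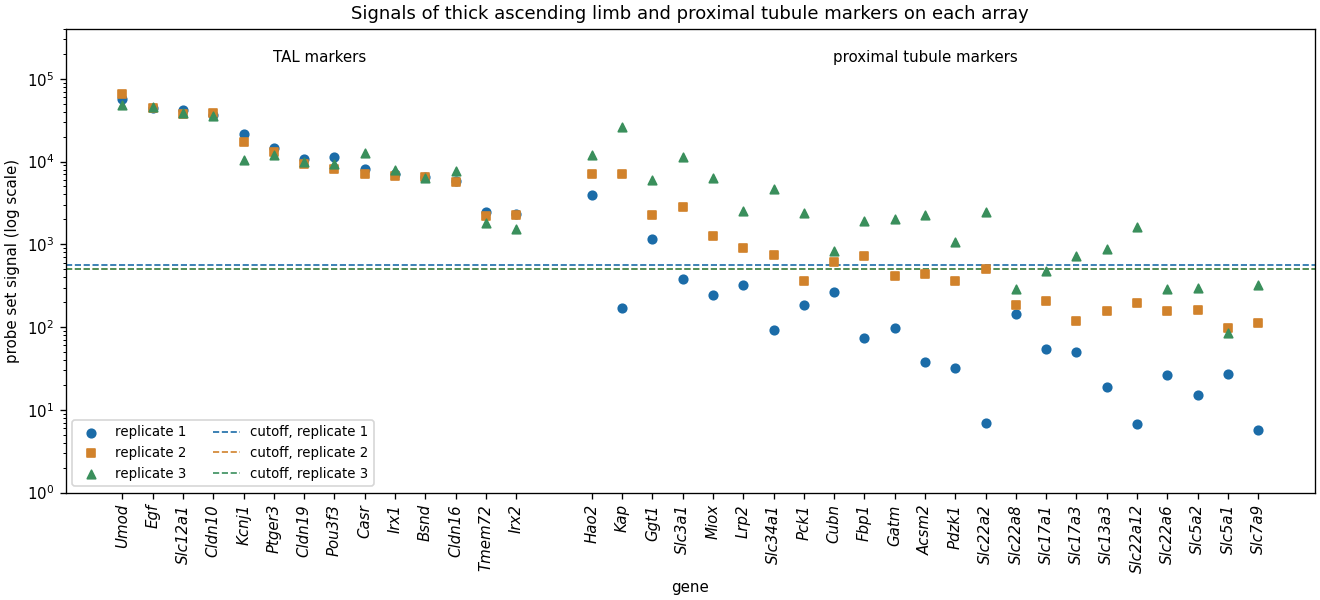
Probe set signal (log scale) of the 14 TAL markers and the 23 measured proximal tubule markers, 1 point per gene and array, with the cutoff of each array as a dashed line (those of replicates 2 and 3, at 501 and 503, overlap). All TAL markers lie above the cutoffs on every array, while 2, 10 and 17 of the 23 proximal tubule markers do on replicates 1, 2 and 3.

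Genes of transepithelial transport gave a mixed picture, in which particular family members were detected. Of 11 sodium pump subunits 4 were detected, with the beta subunit Atp1b1 (53319 ± 7183), the regulators Fxyd2 (42591 ± 3576) and Fxyd6 (14557 ± 315) highest, while Fxyd7 (36.5 ± 29.0) and the alpha subunit Atp1a4 (34.4 ± 34.5) had the lowest signals (adjusted p = 1 for both). Of 19 tight junction genes 13 were detected, among them Cldn10, Ocln (18372 ± 2032) and Cldn8 (13550 ± 138), and the lowest were Cldn18 (75.7 ± 51.3) and Tjp3 (21.2 ± 9.94). Among 15 potassium channel genes 5 were detected, led by Kcnj16 (17832 ± 336), Kcnj1 and the sodium-activated channel Kcnt1 (3632 ± 842), and the lowest were Kcnn4 (39.8 ± 21.8) and Kcne1 (11.2 ± 8.23). Of 13 acid-base genes 6 were detected, led by the carbonic anhydrase Car2 (16562 ± 1695), the apical sodium-proton exchanger Slc9a3 (15548 ± 556) and the sodium bicarbonate cotransporter Slc4a7 (7804 ± 746). The acid-base genes with the lowest signal were Car12 (244 ± 101) and Slc9a4 (76.4 ± 7.17). The counts were the same when adjusted over the list alone. With the cutoff at the 90th percentile, 8 sodium pump subunits and 10 acid-base genes were detected, and at the 99th percentile 4 tight junction genes, 1 potassium channel gene and 2 acid-base genes were. A gene not called detected may still be expressed below what this cutoff can show. Of all genes, 48.3% were detected, and only the tight junction list had a high level, at percentile 99.4 of the random lists. The sodium pump list lay at percentile 35.6, the acid-base list at 27.0 and the potassium channel list at 5.35.

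Receptors and their effectors were likewise detected for part of each family. Of 29 hormone and autacoid receptor genes 14 were detected, led by Ptger3, Casr and the thyroid hormone receptor gene Thrb (6558 ± 1247, adjusted p = 0.000223). The lowest were Glp1r (32.2 ± 30.7) and Ptger2 (11.5 ± 4.27), whose log2 signals minus the cutoff were -4.43 and -5.58. Adcy6 (4292 ± 372, adjusted p = 0.000218) was the only one of 7 measured adenylyl cyclases, the enzymes that make cyclic AMP, that was detected, and the lowest of the family were Adcy5 (49.8 ± 22.9) and Adcy8 (22.4 ± 27.9). Of 12 genes of the WNK-SPAK pathway, which controls the phosphorylation of sodium chloride cotransporters, 9 were detected, led by the sorting receptor Sorl1 (29663 ± 1588), the ubiquitin ligase scaffold Cul3 (8448 ± 412) and the kinase Stk39 (6955 ± 1189). Counts adjusted over the list alone were the same. Of all genes, 48.3% were detected, so the share of receptor genes was no higher than that of genes at large. The level of the receptor list lay at percentile 28.5 of the random lists, that of the adenylyl cyclases at 6.31 and that of the WNK-SPAK list at 99.3. With the cutoff at the 99th percentile, 1 receptor gene, 0 adenylyl cyclases and 1 gene of the WNK-SPAK list were detected, and with the cutoff at TrpnX 25 receptor genes and 4 adenylyl cyclases were.

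**Figure D2:**
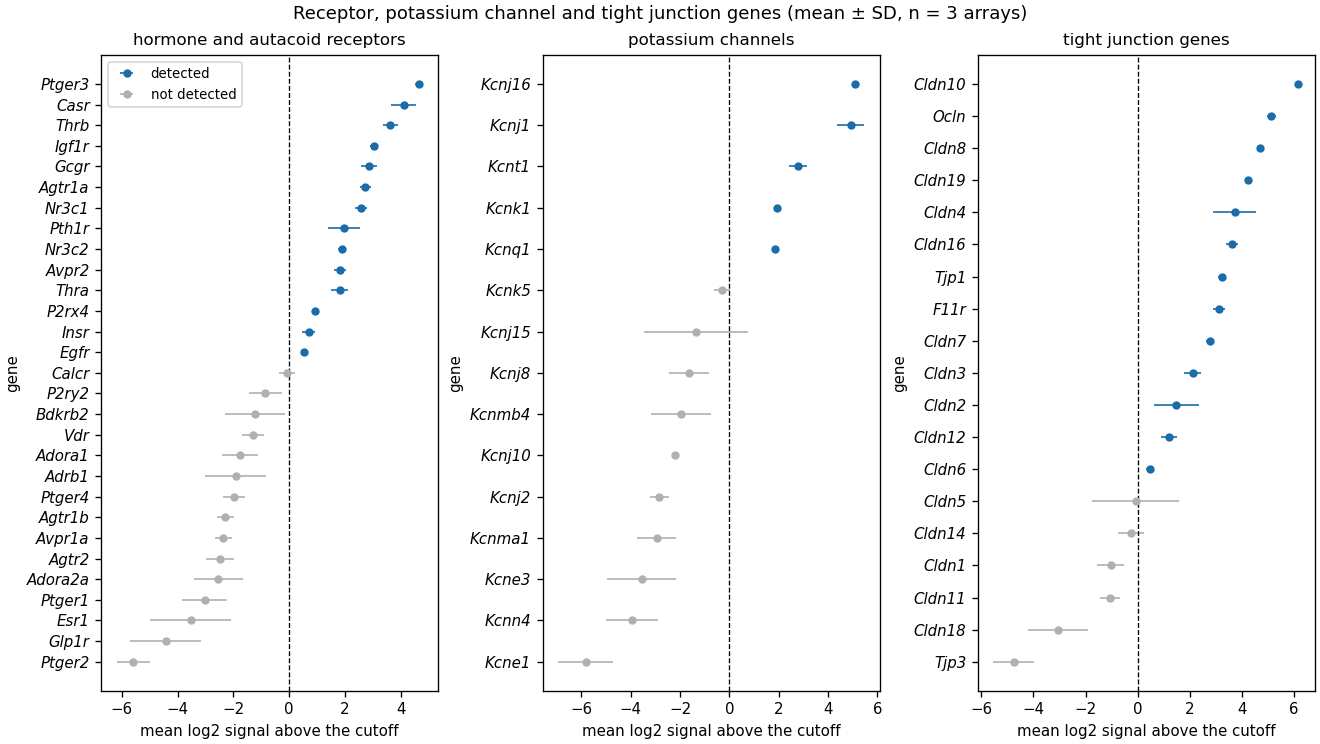
Mean log2 signal above the cutoff, with bars of 1 SD over the 3 arrays, for the 29 receptor, 15 potassium channel and 19 tight junction genes. Detected genes are blue (14, 5 and 13 genes), others are grey, and the dashed line is the cutoff, above which Ptger3 stood at 4.66, Kcnj16 at 5.10 and Cldn10 at 6.15.

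Genes of oxidative phosphorylation, glycolysis and fatty acid oxidation had high signals. All 25 measured subunits of oxidative phosphorylation were detected, with Atp5f1b (50046 ± 1917), Atp5f1c (44850 ± 2443) and Cox4i1 (44814 ± 3000) highest, and the list lay 5.32 ± 0.15 log2 units above the median gene. Of 13 glycolysis genes 12 were detected, led by Aldoa (49165 ± 3933), Ldhb (48777 ± 1128) and Pgk1 (31845 ± 592), at a list level of 4.83 ± 0.19. Of 14 fatty acid oxidation genes 13 were detected, led by Acadm (25189 ± 2463), Hadhb (20170 ± 3366) and Etfb (19124 ± 2279), at a list level of 4.02 ± 0.16. Each of these 3 lists lay above all 10000 random lists. Since no other tissue was profiled, these levels cannot show a trait particular to the mTAL. Of the 3 measured gluconeogenesis genes, Pc (923 ± 156, adjusted p = 0.00848) was detected and the others, which are also proximal tubule markers, were not.

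Most immediate early, heat shock, osmoprotective and transcription factor genes were detected. Of 19 immediate early and heat shock genes 18 were detected, led by Hspa1a (43652 ± 4547), Egr1 (32270 ± 5918) and Dnajb1 (27715 ± 402), and the list level of 4.22 ± 0.55 was above all random lists. Of 5 osmoprotective genes 4 were detected, led by the inositol transporter Slc5a3 (25814 ± 3641), the transcription factor Nfat5 (15076 ± 2652) and the aldose reductase Akr1b1 (2753 ± 858). Of 9 tubule injury genes 4 were detected, with Spp1 (31926 ± 13753), Clu (5171 ± 1855) and Lcn2 (2479 ± 1115) highest, and this count was 2 without replicate 3 and 6 without replicate 1. Of 21 kidney transcription factor genes 15 were detected, led by Esrrg (17330 ± 2740), Tfap2b (10697 ± 1819) and the coactivator Ppargc1a (10042 ± 603). The counts were the same when adjusted over the list alone. The list level lay at percentile 93.3 of the random lists for osmoprotective genes and at 64.0 for tubule injury genes. No untreated tissue was profiled, so these signals have no level to be compared with. With the cutoff at the 99th percentile, 10 of the immediate early and heat shock genes and 4 of the transcription factor genes were detected.

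Markers of other kidney cells were detected in smaller shares, with thin limb and endothelial genes highest. Of 6 thin limb markers 4 were detected, led by Cryab (19659 ± 6806), the water channel Aqp1 (17342 ± 10681) and Fst (5326 ± 2836). Of 11 endothelial markers 6 were detected, led by Esam (5938 ± 727), Plvap (4582 ± 1135) and Emcn (4368 ± 1649), and of 12 principal cell markers 5, led by Tfcp2l1 (7305 ± 1639), the water channel Aqp2 (4310 ± 3229) and the vasopressin receptor Avpr2 (1856 ± 274), a gene known from the TAL as well. Among 18 leukocyte markers Cd74 (25344 ± 2233), Lyz2 (1661 ± 776) and Laptm5 (884 ± 266) were detected, and among 8 podocyte markers Podxl (1432 ± 348), Cdkn1c (1232 ± 347) and Plce1 (729 ± 110). The high signal of Cd74 was not shared by the leukocyte list. Its level was -2.13 ± 0.11 log2 units relative to the median gene, at percentile 1.40 of the random lists. Cspg4 (991 ± 157) was the only detected gene of 13 fibroblast and mural cell markers, Hbb (2835 ± 2641) the only one of 5 red blood cell markers, and Hao2 (7724 ± 4140) and Ggt1 (3134 ± 2546) were those of 23 proximal tubule markers. By limma, 0 of 8 distal convoluted and connecting tubule markers and 0 of 9 intercalated cell markers were detected, and 0 of either list had an unadjusted p under 0.05. Adjusted over the list alone, 1 proximal tubule, 1 leukocyte and 0 red blood cell markers were called, and the other cell type lists had the same counts. Of the 70 other-tissue genes 4 were above the cutoff (3 adjusted over the list alone). The cutoff was set as a percentile of these same genes, so the number above it on each array was fixed by construction. The count is therefore not a measured background rate. The 3 highest of the 70 were Myh1 (42933 ± 2949), Cela1 (1800 ± 324) and Krt10 (1210 ± 125).

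These counts depended on single arrays and on the cutoff. Proximal tubule markers numbered 4 without replicate 1 and 1 without replicate 2, principal cell markers 3 without replicate 2, podocyte markers 1 without replicate 2, endothelial markers 5 without replicate 2 or without replicate 3, and leukocyte markers 1 without replicate 2 or without replicate 3. Fibroblast and mural cell markers numbered 2 and intercalated cell markers 1 without replicate 1, and the red blood cell count was 0 without replicate 2. At the 90th percentile of the other-tissue genes the counts were 7 of 23 for proximal tubule, 9 of 12 for principal cells, 10 of 11 for endothelium, 6 of 13 for fibroblasts and mural cells, 6 of 18 for leukocytes, 3 of 9 for intercalated cells and 1 of 8 for the distal convoluted and connecting tubule.

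The TAL list lay above each of the 10 other cell type lists on all 3 arrays. The difference of list medians was 1.27 ± 1.01 log2 units against thin limb markers (0.78 without replicate 1), 2.91 ± 0.87 against endothelial, 3.46 ± 1.02 against principal cell and 4.68 ± 2.43 against proximal tubule markers. It was 5.12 ± 1.49 against fibroblast and mural cell, 5.42 ± 0.64 against podocyte, 5.50 ± 0.46 against intercalated cell and 6.01 ± 0.19 against leukocyte markers. Against distal convoluted and connecting tubule markers it was 6.57 ± 0.48, and against red blood cell markers 7.77 ± 1.44. The exact sign-flip permutation test gave p = 0.25 for every list, the smallest that 3 arrays allow, so none could pass 0.05. The lists rest on different probe sets, which differ in how strongly they hybridise, so the differences are of signal and do not measure relative expression, and among detected genes only the difference against thin limb markers was 0.22.

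**Figure D3:**
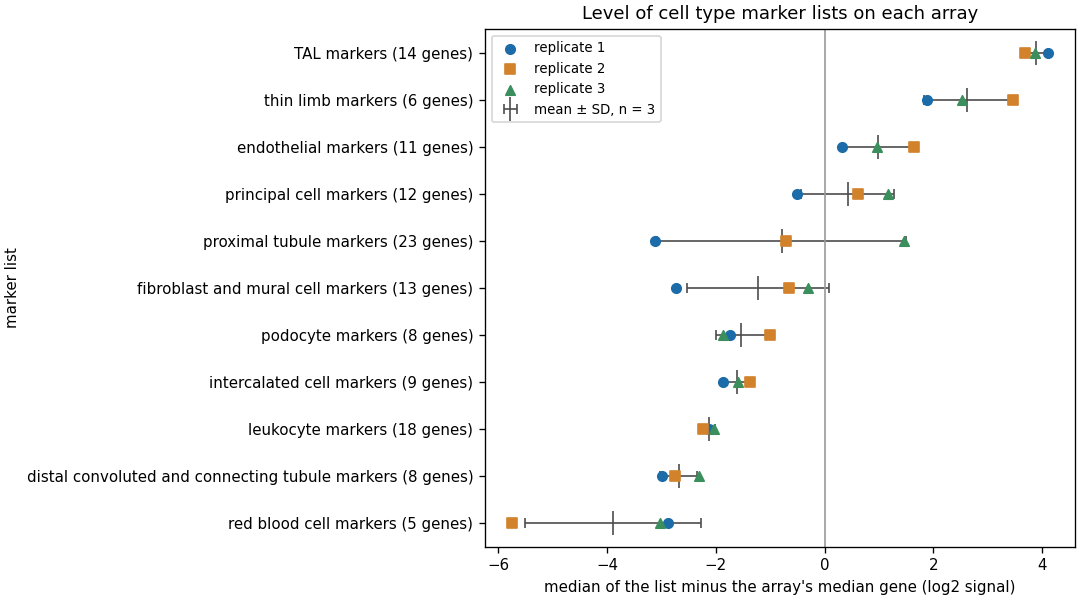
Level of the TAL list and of 10 lists of other cell types on each array, as the median of the list minus the array's median gene in log2 signal, with the mean and a bar of 1 SD over 3 arrays. The TAL list lies at 3.88 ± 0.21, above every other list on each array, and the proximal tubule list spans from -3.13 on replicate 1 to 1.47 on replicate 3.

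The preparations differed most in proximal tubule genes. All 23 proximal tubule markers had a higher signal on replicate 3 than on replicate 1, and with each array centred on its median gene the median difference was 4.28 log2 units, or 19.4-fold, with a middle range over genes from 2.94 to 5.50 (without centring, 4.40 log2 units, or 21.0-fold). On replicate 1 only 2 of the 23 were above the cutoff, so these sizes rest on signals below it and are not measured folds. The androgen-regulated kidney gene Kap had signals of 169, 7164 and 26093 on replicates 1, 2 and 3, Slc3a1, a subunit of the cystine transporter, 381, 2821 and 11459, and the phosphate transporter Slc34a1 91.9, 752 and 4684 (these 3 genes were chosen after their values were seen). The list's deviation was -3.45 on replicate 1, below all 10000 random lists matched on mean level, and 3.15 on replicate 3, above all of them. The sizes of these deviations also rest on replicate 1 signals below the cutoff, and with a pseudocount of 16 the value on replicate 1 was -2.96. The gluconeogenesis genes, of which 2 of 3 are proximal tubule markers, deviated by 2.99 on replicate 3. With the same arrays, TAL markers deviated by 0.20, -0.05 and -0.12 on replicates 1, 2 and 3, each within the middle 95% of the matched lists. For replicate 3 minus replicate 1 the median difference of TAL markers was -0.26, with 3 of 14 genes higher on replicate 3. That lay at percentile 2.58 of the matched lists, close to the lower bound of the middle 95%. The log2 ratio of the 3' to the 5' control probe set of Actb, a sign of RNA degradation when high, was 1.48, 1.18 and 1.95 on replicates 1, 2 and 3, and that of Gapdh 0.51, 0.43 and 0.60. Because each array is a single preparation, the deviations have no replicate test.

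Other lists stood apart on single arrays as well. On replicate 2, thin limb markers deviated by 1.25, endothelial markers by 0.68, with 11 of 11 genes above the mean of the other arrays, and tubule injury genes by 0.76, each above all matched lists. On replicate 3, principal cell markers deviated by 1.18, with 10 of 12 genes above that mean, and immediate early and heat shock genes by 0.62, with 16 of 19 above it, again above all matched lists. On replicate 1, fibroblast and mural cell markers deviated by -1.64, thin limb markers by -1.12, principal cell markers by -1.09, endothelial markers by -0.90 and immediate early and heat shock genes by -0.52, below all matched lists. The 10 detected genes with the largest SD were Adamts1, Hbb, Mgp, S1pr1, Aqp2, Glul, Ggt1, Rnd1, Klf2 and Angptl4, with SDs from 1.28 log2 units for Adamts1 to 1.11 for Angptl4. Adamts1, a secreted protease, had signals of 917, 1869 and 5383 on replicates 1, 2 and 3, and Angptl4, an inhibitor of lipoprotein lipase, 2381, 4523 and 11071. Mgp, a calcification inhibitor of vessel walls, had signals of 1776, 9992 and 5242, and the endothelial receptor gene S1pr1 733, 4107 and 1992. Glul and the transcription factor gene Klf2 were lowest on replicate 1 (794 and 1267), and Rnd1 (4668) and Hbb (5881) highest on replicate 3.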

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

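The limma fit with a mean-variance trend and the counts on single arrays were chosen after seeing the data. No paired analysis was possible because the samples form 1 group. The TAL list lay above each of the 10 other cell type lists under every alternative run for it, of which the filter for detected genes could be run for 5 lists, since the others had fewer than 3 detected genes, and the number of detected genes was 6991 with the trend and 6311 to 6750 when 1 array was left out. The cutoff had the most effect on counts, and the signal over it limits what can be called. At the 99th percentile of the other-tissue genes, which lies between the values of the 2 highest of 70 genes, Myh1 among them, 723 genes were detected, with 7 TAL, 0 proximal tubule, 1 thin limb, 0 principal cell, 0 podocyte, 0 endothelial, 0 fibroblast and mural cell, 1 leukocyte and 0 red blood cell markers. It left 0 gluconeogenesis, 4 tight junction, 1 receptor, 0 adenylyl cyclase, 1 potassium channel, 1 WNK-SPAK, 2 acid-base, 2 osmoprotective, 10 immediate early and heat shock, 1 tubule injury and 4 transcription factor genes. At the highest TrpnX probe set, 11138 genes were detected, with 18 proximal tubule, 5 distal convoluted and connecting tubule, 11 principal cell, 6 intercalated cell, 5 podocyte, 10 endothelial, 11 fibroblast and mural cell, 11 leukocyte and 2 red blood cell markers. It also gave 3 gluconeogenesis, 9 sodium pump, 25 receptor, 4 adenylyl cyclase, 10 potassium channel, 12 acid-base and 8 tubule injury genes. At the 90th percentile the counts were 7 proximal tubule, 1 distal convoluted and connecting tubule, 9 principal cell, 3 intercalated cell, 10 endothelial, 6 fibroblast and mural cell and 6 leukocyte markers, 8 sodium pump subunits, 2 adenylyl cyclases and 10 acid-base genes. On replicate 2 by itself, 10 proximal tubule, 8 principal cell, 3 intercalated cell, 10 endothelial, 6 fibroblast and mural cell and 5 leukocyte markers, 2 gluconeogenesis genes and 7 sodium pump subunits were above the cutoff. On replicate 3 by itself these were 17 proximal tubule, 9 principal cell, 4 intercalated cell, 7 fibroblast and mural cell and 5 leukocyte markers and 3 gluconeogenesis genes. When 1 array was left out, the counts ran from 1 to 4 for proximal tubule, 3 to 7 for principal cell, 0 to 1 for intercalated cell, 1 to 2 for podocyte, 5 to 8 for endothelial, 1 to 2 for fibroblast and mural cell, 1 to 4 for leukocyte, 0 to 1 for red blood cell and 2 to 6 for tubule injury genes. Without probe sets that can match several transcripts, 1 proximal tubule, 1 podocyte, 0 red blood cell and 2 tubule injury genes were detected, the TAL list exceeded thin limb markers by 2.43, and tubule injury genes deviated by 0.23 on replicate 3 in place of a negative value. With the median over probe sets, 2 fibroblast and mural cell markers were detected, the TAL level was 4.29, and the TAL list exceeded thin limb and podocyte markers by 2.29 and 6.27. Among detected genes only, whose median is higher by construction, the TAL level was 2.14, and the TAL list exceeded thin limb, principal cell, podocyte, endothelial and leukocyte markers by 0.22, 2.34, 3.05, 1.74 and 2.69. With that filter the list level turned positive for receptors (0.25), potassium channels (0.67) and acid-base genes (1.78), because it removes the dim genes of each list. Also with that filter, the deviation changed sign for podocyte markers (0.25) and receptors (0.029) on replicate 3, sodium pump subunits on replicate 1 (0.00256) and tight junction genes on replicate 2 (-0.13), and the cause was not tested. A pseudocount of 16 gave proximal tubule markers a deviation of -2.96 on replicate 1. The median correlation of array pairs was 0.954 with that pseudocount, 0.970 among detected genes, 0.950 as Spearman's rho and 0.923 to 0.927 with 1 array left out. The level of the proximal tubule list, -0.79 over all arrays, ran from -1.92 to 0.38 when 1 array was left out. Shifting arrays to a common 75th percentile can change no count or level, since cutoff and median move with it.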

Other observations

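Genes of inflammatory signalling and of cholesterol synthesis also varied between the preparations. These lists were put together after the most deviating genes had been seen, and contain several of them, so their values are a description and not a test, and the genes named here were also picked after their values were seen. Of 15 measured targets and members of the NF-kappaB and interferon pathways, 11 were detected. Irf1, an interferon-induced transcription factor, had signals of 4465, 8649 and 17765 on replicates 1, 2 and 3, the inhibitor Nfkbia 3590, 6692 and 14159, and the chemokine Cxcl10 1033, 2266 and 4809. The list deviated by -1.34 on replicate 1, with 1 of 15 genes above the mean of the other arrays, and by 1.18 on replicate 3, with 13 of 15 above it, while Nfkb1 and Sod2 were not. Replicate 3 also had the highest log2 3' to 5' ratio of all 3 control genes (Actb 1.95, Gapdh 0.60 and hexokinase 1.73). Of 16 measured cholesterol synthesis genes 14 were detected, and with each array centred on its median gene the list deviated by 0.43 on replicate 1, with 15 of 16 genes above the mean of the other arrays, by -0.36 on replicate 2, with 2 of 16 above it, and by -0.07 on replicate 3. Sqle, the squalene epoxidase, had signals of 2124, 1079 and 1389, and Msmo1 6832, 3778 and 5142.

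Tests on the proximal tubule genes for noise, for the share of thick limb cells and for RNA integrity were chosen only after the difference had been seen, whereas the tests of carry-over and of Myh1 were written down before their results.

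Carry-over of other cells was tested for 8 cell types, with the prediction that at least 50% of a type's measured markers are detected, since whole cells bring all their abundant transcripts, although the Percoll step is meant to remove such cells. The detected share was 0% for intercalated cells, 0% for the distal convoluted and connecting tubule, 16.7% for leukocytes, 8.70% for proximal tubule, 7.69% for fibroblasts and mural cells, 37.5% for podocytes, 41.7% for principal cells and 54.5% for endothelium. The bound of 50% was judged wrong after the results were seen, because the share depends on the cutoff: at the TrpnX cutoff it was 61.1% to 91.7% for these types, with 25.7% of the other-tissue genes also above it. At that cutoff 11138 of all 14217 genes were detected, so the shares there do not mark these types out from genes at large. Single arrays mattered too, since 73.9% of proximal tubule markers were above the cutoff on replicate 3, and 5 of 11 endothelial markers, under the bound, were detected without replicate 2 or without replicate 3. Carry-over therefore stays open for all 8 types, most of all at levels near the cutoff.

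Proximal tubule cells carried over in different amounts are a candidate explanation for the difference of 4.28 log2 units between replicates 3 and 1, with each array centred on its median gene. The size of that difference is not exact, since only 2 of the 23 markers were above the cutoff on replicate 1. A second list of 21 proximal tubule genes, not looked at before, had a median difference of 1.02 after the same centring, just past the value of 1 that had been set, with 18 of 21 genes higher on replicate 3 (1.14 and 20 of 21 without centring), among them Agxt2 (18.3, 439 and 1400 on replicates 1, 2 and 3) and Dao (38.8, 728 and 1259), the 2 genes of the list with the largest difference, chosen after their values were seen. On replicate 1 both lay below the cutoff of 562, so the size of their difference is not exact. Of that list, 8 genes were detected, and Folr1, Hpd and Dab2 (also chosen after their values were seen) had high signals on all arrays, which the thick limb itself may express. Noise of low signals is argued against, since the difference of the second list lay at percentile 100 of matched random lists. The first list lay at percentile 100 as well, but it had been singled out for its difference, so its rank adds no independent support. Lower RNA integrity of replicate 1 is also argued against. Its log2 3' to 5' ratios were lower than those of replicate 3, by a mean difference of -0.30 ± 0.19 (SD over 3 control genes). A lower share of thick limb cells as the only cause is argued against, since it would raise all other types alike. The proximal tubule median exceeded the mean of the endothelial, leukocyte and podocyte medians by 4.06 and the highest other median, 1.45 for principal cells, by 2.83. These sizes are not exact, since 2 of 23 proximal tubule, 4 of 18 leukocyte and 3 of 8 podocyte markers were above the cutoff on replicate 1. A lower share as a part of the cause stays open, since fibroblast and mural cell (1.31), intercalated cell (0.83), endothelial (0.74) and thin limb markers (0.71) rose as well. TAL markers had a median difference of -0.26 (percentile 2.58 of matched lists) and oxidative phosphorylation subunits one of -0.27 (percentile 0.42). No biological explanation was tested, since the labels give 1 group.

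The gene named Myh1, a myosin heavy chain of skeletal muscle, had a signal of 42933 on its brightest probe set. Muscle tissue in the preparation is argued against, since 0% of 15 other skeletal muscle genes were detected by limma; Tnnt3 and Actn3 are among the 70 genes that set the cutoff, but of the 13 others, not looked at before, 0 were detected, 0 had an unadjusted p under 0.05, 2 were called at the 90th percentile cutoff and 5 at the TrpnX cutoff, with Acta1 at 36.8 and Ckm at 107 (named after their values were seen). The probe set reporting another transcript was to be excluded if the gene's other probe sets were bright too, and 0 of the 4 others were below the cutoff on every array, though 1 of them had a mean of only 1866 ± 459 against 28756 to 34757 for the rest. That bound was judged wrong after the result was seen, because the 5 probe sets rest on 3 sequence records, of which none is a RefSeq transcript, so an error of annotation would be shared by all of them. A true signal of Myh1 and such an error therefore cannot be told apart.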
